A study of Mus musculus with 2 samples.

How the data were processed

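Hi-C, which counts ligation products between DNA fragments that lie close together in the nucleus, was run on 2 samples of HPC5, a mouse haematopoietic progenitor cell line derived from bone marrow, both with wild-type Etv6. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was cut with the restriction enzymes of the Arima kit, the cut ends were filled in with biotin and ligated, and the enriched fragments were sequenced on an Illumina instrument. The samples form 1 group and carry the replicate numbers 1 and 2 in their titles. The labels do not say whether they came from separate cultures, so a difference between them may be technical.

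The submitters' processing notes name HiC-Pro 2.11.1 and the mm10 build. The programs that called loops and domains are not given in the sources used here. For each replicate the authors deposited 2 loop lists, called here the high setting and the medium setting after the terms in their names, and 1 domain list, whose name gives a bin of 5000 bp. Each list belongs to 1 replicate. Each deposited loop is a pair of anchors (bins of 5, 10 or 25 kb) with a whole number tagged n and a value tagged qBL, at most 0.0948 in any list. The files do not define either tag. The number n was larger for wider anchors (medians 19, 29 and 60 at 5, 10 and 25 kb in replicate 2) and was used only to rank loops and to compare the replicates at anchor pairs they shared. Each deposited domain has a rank and a score of 1 or 1000, also undefined, which was not used. The lists give no read or contact totals, so the sequencing depth is unknown and no floor can be stated. Contact matrices were not analysed here.

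Loop coordinates are printed as deposited, and domain starts were moved by one base to count from 1. Loops were called shared when the midpoints of both anchors lay within 20 kb of those of a loop in the other replicate. The span is the distance between the midpoints. Shares carry a 95% Wilson interval, which covers counting error only and treats loops as independent, which neighbouring loops are not. The random expectation came from 10000 circular shifts of the loops, domains or anchors along their chromosomes, with 1 offset per chromosome in steps of 25 kb, which keeps their number, span and clustering. The p-values from these are one-sided permutation p-values, and 0.0001 is the smallest they can give. They compare positions within these lists and not conditions. Genes came from the RefSeq table of GRCm38.p6, the assembly that mm10 names, with 21521 protein-coding genes on the 19 autosomes and X. Left out were 345 genes (110 protein-coding) of unlocalised or alternate scaffolds, whose coordinates are those of the scaffold. Chromosome extents run from the first to the last annotated gene (2570 Mb in all).

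The gene table has no strand. The planned test of transcription start sites was therefore run on gene ends: a gene counted as lying at an anchor when either of its ends did, and one of these is its start. No genome sequence was used, so the planned test of CTCF motif orientation was not run.

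Before the data were examined, 10 gene lists were fixed (stem and progenitor regulators, interferon response, TNF and NF-kB inflammatory response, myeloid, erythroid and megakaryocytic, lymphoid, non-haematopoietic, Hox genes, a list of cell cycle, ribosome and housekeeping genes, and loop extrusion machinery). Of 372 list entries, 368 matched a protein-coding gene. Each list was tested against all other protein-coding genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 10 lists, on the anchors of both replicates' medium lists together. Genes named are Etv6 and, per list, up to 5 members at an anchor of a shared loop in order of span, filled to 3 from single-replicate loops. A gene was at a shared loop when its end lay in that loop's anchor in either replicate, not always in both. Loops named are the 5 longest, the 5 shortest and the 10 with the highest n among shared loops, and the 5 anchors with the most loops. A gene that this rule would name is not reported here. Other genes are marked as chosen after their values were seen. Gene families, grouped by symbol stem, and gene ends at domain boundaries were examined only after the data had been seen.

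Alternatives were other matching distances, overlap of the anchors, the high setting, local shifts of 0.5 to 2 Mb, autosomes alone, gene ends within 5 or 10 kb, each replicate alone, shared loops alone, all annotated genes, and random lists matched on gene density within 500 kb. Added after seeing the data were gene bodies in place of gene ends, random lists matched on density and length, a background without olfactory and vomeronasal receptor genes, and 1 list member per 500 kb. The scripts were tested on simulated data. With 20, 50 and 80% of 1276 simulated loops placed near replicate 2 loops, 21.6, 50.5 and 80.3% were found. These loops were drawn from the replicate 2 list and placed inside the matching tolerance, so the result checks the code only. Of 40 unrelated lists of that size, 0% had a p under 0.05. They were replicate 1 loops moved by the same circular shift that gives the expectation, so they cannot show how the test treats real unrelated lists. Of 200 random lists of 40 genes, 3% passed an unadjusted 0.05 among 21521 genes, and of 200 lists drawn with 4 times the odds of lying at an anchor, 99.5% did. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, networkx 3.6.1 and matplotlib 3.10.9 was used.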

Results

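Chromatin loops and domains were mapped by Hi-C in HPC5 cells, a mouse haematopoietic progenitor line, with wild-type Etv6, the gene of an ETS-family transcriptional repressor needed in blood stem and progenitor cells. The series title places the map in a study of inflammatory gene repression by ETV6. There were 2 replicates and no mutant or treated sample, so the comparisons are between replicates, between loops and domains, and between both and the genes they touch. Under the medium setting replicate 1 listed 1276 loops and replicate 2 listed 5729, or 4.49 times as many. Under the high setting they listed 202 and 3354, a ratio of 16.6. All 202 and all 3354 high-setting loops recurred with the same anchors in the medium lists, whose remaining 1074 and 2375 loops were all called on 25 kb anchors. Replicate 1 had no loop on 5 kb anchors, and replicate 2 had 986. The depth behind the lists is unknown.

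Loops joined anchors a median of 150 kb apart in each replicate, with quartiles of 100 and 250 kb in replicate 1 and of 90 and 280 kb in replicate 2. Under the high setting the median was 110 kb in both. The spans ran from 35 to 1960 kb in replicate 2 and from 50 to 1960 kb in replicate 1. Loops of 1000 kb or more made up 0.94% of the replicate 1 list (12 loops) and 2.18% of the replicate 2 list (125 loops).

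Most loops of replicate 1 were found again in replicate 2. Of its 1276 medium-setting loops, 1029 had a partner with both anchors within 20 kb, which is 80.6% (95% Wilson interval 78.4 to 82.7%), against 0.899% on average and 7.6% at most for shifted loops (permutation p = 0.0001). Of the 202 loops on 10 kb anchors 92.6% were found again, and of the 1074 on 25 kb anchors 78.4%. In the other direction 1041 of 5729 replicate 2 loops, or 18.2% (17.2 to 19.2%), had a partner in replicate 1, against 0.202% for shifted loops (permutation p = 0.0001). Under the high setting 90.6% of replicate 1 loops and 5.52% of replicate 2 loops had a partner. Under the medium setting the share was 35.7% for replicate 2 loops on 5 kb anchors, 22.0% on 10 kb anchors and 7.03% on 25 kb anchors. The 20 kb tolerance is smaller than a 25 kb bin. Loops on 25 kb anchors could thus match each other only at identical anchors, while narrower ones could lie some bins apart. Of the 167 replicate 2 loops on 25 kb anchors that were found, 163 had the same anchors in replicate 1. The shares are therefore not comparable between widths. Among the 25 kb loops the share was 1.85% for the 25% with the lowest n and 14.6% for the 25% with the highest. There was no such order on narrower anchors, where the shares in 4 groups of rising n were 17.1, 25.3, 24.2 and 21.6% at 10 kb and 39.7, 30.9, 29.7 and 42.5% at 5 kb.

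The longest shared loop joined 145550001 to 145559999 and 147510001 to 147519999 on chromosome 4, 1960 kb apart, and its right anchor held an end of Zfp982. The other 4 of the 5 longest spanned 1370 to 1480 kb on chromosomes 13, 2 and 12 and had no protein-coding gene end at either anchor. The 5 shortest shared loops spanned 35 to 50 kb, and each had a gene end at one anchor or both. Their anchors held Niban2 on chromosome 2, Rbpms2 on chromosome 9, Spty2d1 on chromosome 7, Pcp2 and, at the other anchor, Fcor on chromosome 8, and Hnrnpa3, an RNA-binding protein gene, on chromosome 2. The 10 shared loops with the highest n (135 to 171 in replicate 2) all lay on 25 kb anchors and spanned 100 to 175 kb. The first joined 67025001 to 67049999, which held Gadd45a, a DNA damage response gene, to 67125001 to 67149999 on chromosome 6. Others had 1 anchor at Dock5, at Thoc1 and Usp14 together, at Lpl, the lipoprotein lipase gene, or at Kif11, a mitotic kinesin gene. In 2 of the 10 both anchors held a gene end, with Ttc39b joined to Snapc3 and Bbs10 to Nap1l1.

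Etv6 itself lay inside a loop found in both replicates. The gene occupies 134035700 to 134270158 on chromosome 6. In replicate 1 a loop of 425 kb joined 133950001 to 133974999, where no protein-coding gene ends, to 134375001 to 134399999, which held an end of Bcl2l14. In replicate 2 the matching loop of 430 kb joined 133960001 to 133964999 and 134390001 to 134394999. Replicate 2 also listed a domain from 133950001 to 134395000, of 445 kb, which held Etv6 and the predicted gene Gm46977 in full. There were 3 more replicate 2 loops over the gene. One of 480 kb spanned it, and one of 275 kb ended inside it at 134225001 to 134249999. The third, of 100 kb, joined its right end at 134250001 to 134274999 to 134350001 to 134374999. None of these 3 had a partner in replicate 1, whose medium list was 4.49 times shorter.

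**Figure D1:**
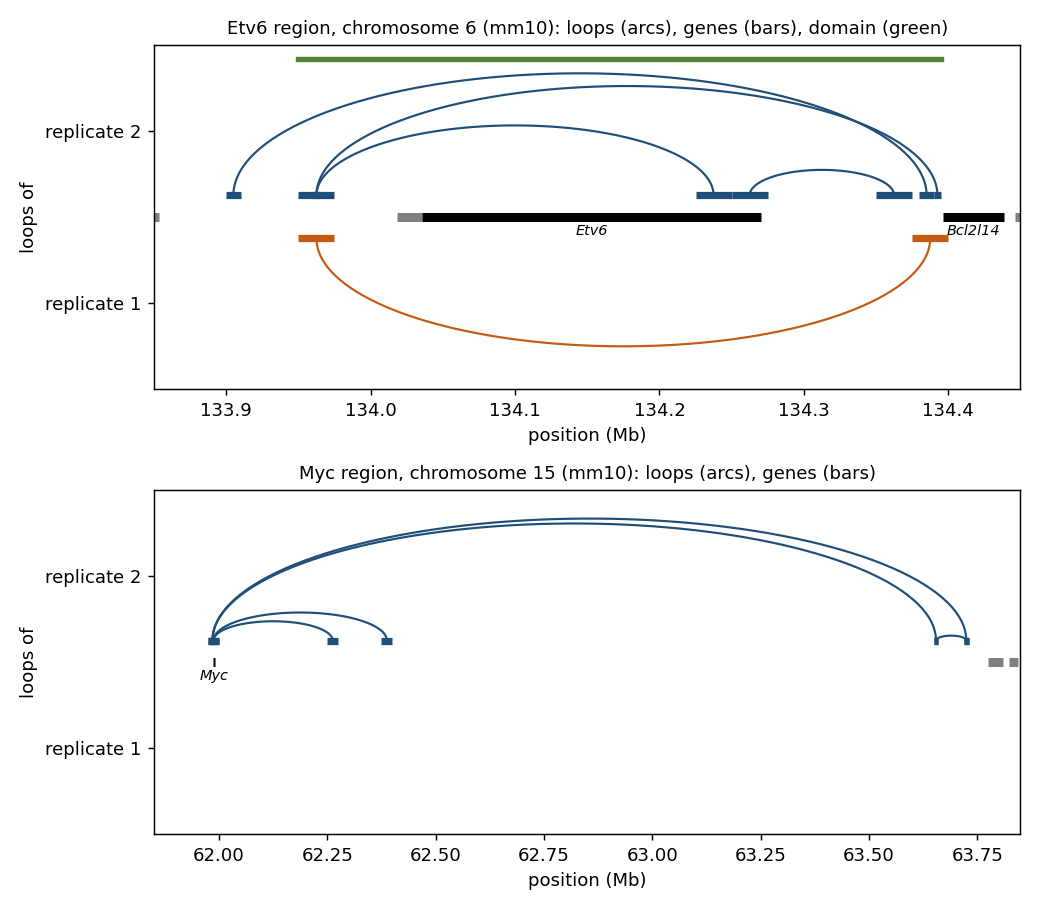
Loops as arcs between anchors (thick ends), protein-coding genes as bars on the middle line and domains in green, against position in Mb on mm10, with replicate 2 above, replicate 1 below and arc height in proportion to span within a panel. The upper panel shows the 425 and 430 kb loops and the 445 kb domain around Etv6, and the lower panel the replicate 2 loops from Myc, the longest of 1740 kb, and a loop between the anchors of the longest pair, with no replicate 1 loop.

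Loop anchors held gene ends more often than shifted anchors did. Of 12263 distinct anchors in both medium lists together, 36.0% (95% Wilson interval 35.2 to 36.9%) held an end of a protein-coding gene, against 17.6% for shifted anchors and at most 20.2% (permutation p = 0.0001). For anchors moved by 0.5 to 2 Mb the expectation was higher, 20.4% on average and 21.8% at most (permutation p = 0.0001). Anchors of different widths that overlap were counted apart. With the circular shifts the share was 21.3% against 7.41% for 5 kb anchors, 30.3% against 13.0% for 10 kb anchors, and 45.8% against 24.9% for 25 kb anchors. It was 44.1% against 23.0% for replicate 1 alone and 34.7% against 16.8% for replicate 2 alone. Both anchors held a gene end in 21.5% of replicate 1 loops and 15.2% of replicate 2 loops, and neither did in 33.9 and 45.3%. No shifted expectation was computed for these shares. They are not comparable between replicates, since 84.2% of replicate 1 loops and 41.5% of replicate 2 loops were on 25 kb anchors. In all, 4851 of 21521 protein-coding genes (22.5%) had an end in an anchor.

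Regulators of blood stem and progenitor cells lay at loop anchors more often than other genes. Of 40 such genes 22 had an end in an anchor, which is 55% (39.8 to 69.3%) against 22.5% of all other genes (odds ratio 4.21, Fisher's exact test, two-sided, p = 8.37e-06, Benjamini-Hochberg adjusted p = 8.37e-05). There were 11 of these genes at anchors in replicate 1, 17 in replicate 2 and 8 at anchors of shared loops. Meis1, a homeobox gene whose protein partners Hox proteins, had its right end at 19015001 to 19019999 on chromosome 11, joined over 140 kb to 18875001 to 18879999 just beyond its left end. Lmo2, which encodes an adaptor of blood transcription factor complexes, was joined over 110 kb from 103980001 to 103984999 to 103870001 to 103874999 on chromosome 2. Lyl1, a basic helix-loop-helix factor gene, shared a 100 kb loop with an anchor at Nfix and Dand5 on chromosome 8. Procr, a surface marker gene of stem cells, lay at the right end of a 100 kb loop on chromosome 2. Cebpe, a granulocyte transcription factor gene, was joined over 70 kb to an anchor at Slc7a8 and Rnf212b on chromosome 14. The ends of Meis1 and Lmo2 lay in anchors of both replicates, with the narrower replicate 2 anchors given here, and those of Lyl1, Procr and Cebpe in replicate 1 anchors.

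Several regulators outside that choice, named after their values were seen, had loops in replicate 2 alone. Myc, a growth-promoting transcription factor gene at 61985341 to 61990361 on chromosome 15, had 4 loops in replicate 2 and 0 in replicate 1. They reached 275, 400, 1670 and 1740 kb to the right of the gene, the farthest anchor lying at 63720001 to 63729999. A stretch far downstream of Myc is known to hold a blood enhancer cluster, and its position was not compared with these anchors. Sox4 on chromosome 13 had loops of 650 and 880 kb. Hoxa9, a homeobox gene of progenitors, had 4 loops of 200 to 1000 kb on chromosome 6, of which the 200 and 350 kb ones ended at an anchor with an end of Skap2. Its 200, 350 and 1000 kb loops started from 52200001 to 52224999, which also held ends of Hoxa3, Hoxa5, Hoxa6 and Hoxa7. Only the 640 kb loop had an anchor, 52220001 to 52229999, with no other listed Hox gene. Spi1, which encodes the myeloid factor PU.1, had a loop of 100 kb to an anchor at Nr1h3, Acp2 and Ddb2 on chromosome 2.

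Genes of the TNF and NF-kB inflammatory response were also at anchors more often than other genes, in both lists together. Of 56 such genes 21 were, which is 37.5% (26.0 to 50.6%) against 22.5% (odds ratio 2.07, Fisher's exact test, two-sided, p = 0.0102, adjusted p = 0.0339). Without replicate 1 the count was 16, with an odds ratio of 1.62 and an adjusted p of 0.321 in the same Fisher's exact test, and without replicate 2 it was 10, with 3.05 and 0.0123. The list also missed the threshold, with odds ratios close to the 2.07 above, when gene bodies were counted (1.75, adjusted p = 0.102), without olfactory and vomeronasal receptor genes in the background (1.90, 0.087) and with 1 member per 500 kb (1.95, 0.115), in the same exact test. Against random lists matched on gene density its odds ratio was 2.09 and its adjusted p, from 10000 such lists, was 0.05, at the threshold and not under it. At shared loops were Il18, a cytokine gene, with a 50 kb loop on chromosome 9, and Ccl9, a chemokine gene, with a 60 kb loop on chromosome 11. Cd69, an activation antigen gene, was joined over 100 kb to Clec12a on chromosome 6. Cxcl1 was joined over 100 kb to an anchor at its fellow chemokine genes Cxcl3 and Cxcl15 on chromosome 5, and Fos, an immediate early gene, had a 100 kb loop on chromosome 12. Replicate 1 anchors are given for these loops, and Il18, Cxcl1 and Fos had no end in a replicate 2 anchor. Cd69 had an end in a replicate 2 anchor only at another loop, of 60 kb, which had no partner in replicate 1. The replicate 2 loop matching that of Cxcl1 spanned 120 kb. It joined Cxcl3 to Cxcl2, another chemokine gene, named after its values were seen. Tnfaip3, a brake on NF-kB signalling that was named after its values were seen, had 4 loops of 50 to 170 kb, all in replicate 2, from 19010001 to 19019999 on chromosome 10.

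Interferon response genes did not differ detectably from other genes. Of 50 such genes 10 were at an anchor, or 20% (11.2 to 33.0%) against 22.5% (odds ratio 0.86, Fisher's exact test, two-sided, p = 0.738, adjusted p = 0.738). All 10 were at anchors of replicate 2, and 2 were also at anchors of replicate 1. At shared loops were Ifngr1, a chain of the interferon gamma receptor, with a 100 kb loop on chromosome 10, and Dhx58, an RNA sensor gene joined over 120 kb to an anchor at Ttc25 and Cnp on chromosome 11. Gbp2, an interferon-induced GTPase gene, was joined over 130 kb to its relative Gbp5 on chromosome 3. The loop of Dhx58 is given for replicate 1, and those of Ifngr1 and Gbp2 for replicate 2. In replicate 2 the matching loop of Dhx58, of 130 kb, had no protein-coding gene end at its other anchor. Ifngr1 had no end in a replicate 1 anchor.

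Hox genes, the homeobox genes that lie in 4 clusters, had ends in anchors in 20 of 39 cases, or 51.3% (36.2 to 66.1%; odds ratio 3.63, Fisher's exact test, two-sided, p = 0.000128, adjusted p = 0.000641). There were 6 genes in the Hoxa cluster, 4 in Hoxb, 5 in Hoxc and 5 in Hoxd. Neighbouring Hox genes share anchors, so the test counts them as more independent than they are, and with 1 gene per 500 kb the list held 4 genes, 1 of them at an anchor (odds ratio 1.15, adjusted p of the same exact test 1). Under the high setting the odds ratio was 2.46 and the adjusted p 0.071. In replicate 1 Hoxc6, Hoxc8 and Hoxc9 sat in 1 anchor on chromosome 15, at 102975001 to 102999999, which was joined over 175 kb to Smug1. Also in replicate 1, Hoxb3 and Hoxb4 sat in 1 anchor on chromosome 11, at 96300001 to 96324999, with a loop of 250 kb. Ends of Hoxb5 and Hoxb6, named after their values were seen, lay in the same anchor. The matching replicate 2 loop had a 5 kb anchor with ends of Hoxb5 and Hoxb6, and not of Hoxb3 or Hoxb4.

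The list of cell cycle, ribosome and housekeeping genes had 15 of 38 genes at anchors, or 39.5% (25.6 to 55.3%; odds ratio 2.24, Fisher's exact test, two-sided, p = 0.0184, adjusted p = 0.046). It missed the threshold in 6 of 11 alternatives, with odds ratios of 1.70 to 3.17 over the 11. Without replicate 1 the adjusted p of the same exact test was 0.129. Atp5b, Rps3, Rpl3, Hprt and Ccnd2 lay at shared loops of 100 to 225 kb. The remaining 5 lists did not pass the adjusted threshold. Genes listed as loop extrusion machinery were at anchors in 6 of 14 cases (42.9%, adjusted p = 0.202, Fisher's exact test). Among them were Mau2, Stag2 and Nipbl, which encode subunits or loaders of cohesin. Yy1, a transcription factor gene named after its values were seen, was also among the 6. Genes listed as erythroid and megakaryocytic were at anchors in 9 of 26 cases (34.6%, adjusted p = 0.263, Fisher's exact test), with Nfe2l2, Tfrc, the transferrin receptor gene, Gp1ba and Bpgm at shared loops of 70 to 250 kb. Nfe2l2 encodes a broadly expressed stress-response factor and is not a marker of these lineages. On shared loops alone this list passed, with an odds ratio of 3.86 and an adjusted p of 0.0393 in Fisher's exact test. That rests on 5 of 26 members, Nfe2l2 among them, and was not tested without it. Lymphoid genes gave 8 of 32 (25%, adjusted p = 0.738, Fisher's exact test), with Cd2 and Eomes at shared loops and Cd4 at a replicate 2 loop. Myeloid genes gave 5 of 30 (16.7%, adjusted p = 0.649, Fisher's exact test), with Itgam, the CD11b gene, at a shared loop and Csf1r and Ngp at replicate 2 loops. Genes of non-haematopoietic tissues gave 6 of 43 (14.0%, adjusted p = 0.292, Fisher's exact test), with Krt8 at a shared loop and Mbp and Vil1 at replicate 2 loops.

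**Figure D2:**
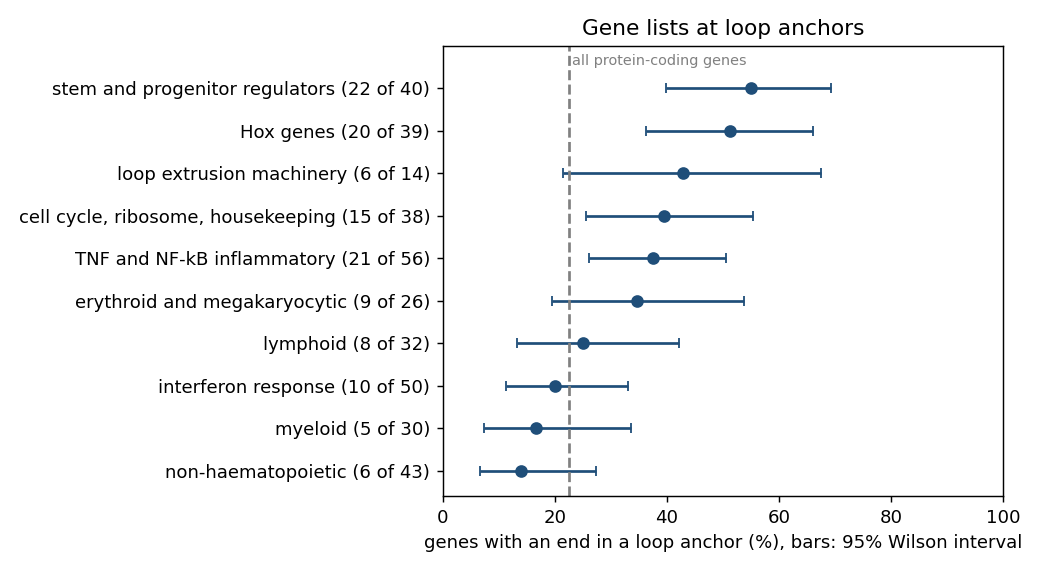
Share of each gene list with a gene end in a loop anchor of either replicate (percent, medium setting), with 95% Wilson intervals, and the share of all protein-coding genes, 22.5%, as a dashed line. Stem and progenitor regulators are highest at 55% and genes of non-haematopoietic tissues lowest at 14.0%.

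Most anchors took part in 1 loop: 10745 of the 12263 distinct anchors (87.6%). Only anchors with identical coordinates were counted as 1. Overlapping anchors of different widths were counted apart, which raises that share and lowers the loops per anchor. With the loops of both replicates added, so that a loop found in both at the same anchor counts once in each, the anchor with the most loops, 6, lay at 22025001 to 22049999 on chromosome 13. It held ends of the histone genes H2ac12, H2bc12, H4c9, H2ac11 and H2bc11. Its loops spanned 200 to 1725 kb, 5 of them in replicate 2 and 1 in replicate 1. Anchors with 5 loops each lay at 61525001 to 61549999 on chromosome 8 and 116375001 to 116399999 on chromosome 9, with 2 in replicate 1 and 3 in replicate 2 at each, and held no protein-coding gene end. There were 20 anchors with 4 loops, the first in chromosome order being those at Lhx9, a homeobox gene, and at Uchl5, a proteasome-associated deubiquitinase gene, both on chromosome 1.

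Domains were few in both lists, and the 3 domains of replicate 1 were all present in replicate 2. These lay at 44725001 to 45160000 on chromosome 16, and at 13280001 to 13600000 and 78955001 to 79265000 on chromosome 2. All 6 of their boundaries lay within 25 kb of a replicate 2 boundary, against 1.47% for shifted domains (permutation p = 0.0001). Replicate 2 listed 339 domains of a median of 365 kb (quartiles 320 and 460 kb), which covered 127 Mb or 4.94% of the annotated extent, and the 3 of replicate 1 covered 0.0414%. In replicate 2 a loop joined both corners of 156 of 339 domains within 25 kb, or 46.0% (40.8 to 51.3%), against 0.628% for shifted domains (permutation p = 0.0001). The share was 20.6% within 10 kb, 63.1% within 50 kb and 34.2% under the high setting. In replicate 1 a loop joined the corners of all 3 domains within 25 kb, and of 1 of the 3 within 10 kb or under the high setting.

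The X chromosome had the lowest loop density in each replicate. Replicate 2 listed 0.829 loops per Mb on X, against 1.86 to 3.43 on the autosomes. Replicate 1 listed 0.161 per Mb, against 0.378 to 0.772. Chromosome 11 was highest in replicate 2 at 3.43 per Mb and chromosome 19 in replicate 1 at 0.772. Domains in replicate 2 numbered 4.18 per 100 Mb on X and 7.99 to 25.9 on the autosomes, with chromosome 10 highest.

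**Figure D3:**
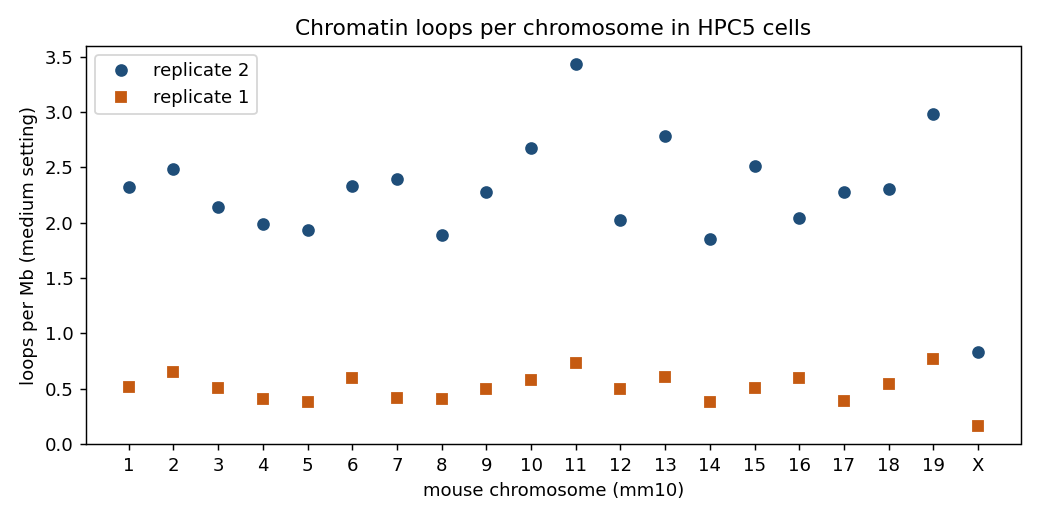
Medium-setting loops per Mb of annotated extent on each mouse chromosome, for replicate 1 (squares) and replicate 2 (circles). X is lowest in both, at 0.161 and 0.829 loops per Mb.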

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

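Tests with gene bodies in place of gene ends, without olfactory and vomeronasal receptor genes, with 1 list member per 500 kb, and against random lists matched on gene density and length were chosen after seeing the data. No paired analysis was possible because both samples belong to the same group. The sharing of loops and of domain boundaries between replicates, loops at domain corners, and gene ends at anchors stayed above the shifted expectation with a p under 0.05 under each alternative run. The share of replicate 1 loops found in replicate 2 ran from 60.5% at 10 kb to 94.6% at 50 kb, and the reverse share from 5.52% under the high setting to 23.3% at 50 kb. Loops at replicate 2 domain corners ran from 20.6% at 10 kb to 63.1% at 50 kb, and in replicate 1 from 33.3 to 100%. Gene ends at anchors ran from 27.7% under the high setting to 59.9% within 10 kb. The mean of both median spans, 150 kb, became 110 kb under the high setting, 155 kb for shared loops and 97.5 kb for the narrowest anchors of each list. That follows from the anchor widths kept in the first and last case, and for shared loops the cause was not tested. The number of gene lists past the threshold, 4, became 2 under the high setting, 2 to 4 when either replicate was left out, 5 on shared loops and 2 against random lists matched on gene density. It also became 2 when gene bodies replaced gene ends, 2 without olfactory and vomeronasal receptor genes in the background, and 1 with 1 list member per 500 kb. The cause of these changes was not tested. In the last, the Hox list fell to 4 genes and the TNF and NF-kB list to 47, and the housekeeping list, unchanged at 15 of 38 with an unadjusted p of 0.0184 in the exact test, missed the threshold through the adjustment. The stem and progenitor regulators passed in 11 of 11 alternatives (odds ratios 3 to 5.34), Hox genes in 9, the TNF and NF-kB list in 6 (adjusted p of the exact and random-list tests 0.00303 to 0.321) and the housekeeping list in 5. The test of CTCF motif orientation was not run, for want of a genome sequence. Without read totals, what depth limits cannot be put in numbers.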

Other observations

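The tests of loop numbers in both replicates, those of X except the one on loops per gene, and those of gene families and domain boundaries were chosen after the results were seen, and, of the tests on the stem and progenitor list, those without its Hox genes, without receptor genes and against lists matched on density and length were chosen after its enrichment was seen, while the high setting was planned.

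Several large gene families, found by comparing all symbol stems, were scarce at loop anchors. Olfactory receptor genes, named by the stem Olfr, had an end in an anchor in 32 of 1109 cases (2.89%, odds ratio 0.0961, Fisher's exact test, two-sided, adjusted p = 1.54e-79), against 23.6% of other protein-coding genes. Vomeronasal receptor genes (Vmn) did in 5 of 352 cases (1.42%, adjusted p = 4.25e-30, same exact test). Keratin-associated protein genes (Krtap) gave 1 of 56, Pramel genes 0 of 46, Rhox homeobox genes 0 of 33, alpha-defensin genes (Defa) 0 of 28, prolactin family genes (Prl) 0 of 25 and cytochrome P450 genes (Cyp) 11 of 99. Of 111 symbol stems with at least 20 members, 12 passed the adjusted threshold, 10 below the other genes and 2 above. The 2 above were Cep, centrosomal protein genes with 17 of 38, and Tbc, with 14 of 30. Members of most of these families lie side by side, so the exact tests overstate their independence. The tests also took no account of chromosome or of how well reads map to these genes. Few listed loops there need not mean few loops.

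Domain boundaries in replicate 2 lay near genes. Of 678 boundaries 69.5% (95% Wilson interval 65.9 to 72.8%) had a protein-coding gene end within 25 kb, against 37.0% for shifted boundaries and 39.5% for boundaries moved by 0.5 to 2 Mb (permutation p = 0.0001 for each).

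Replicate 1 listed 1276 loops and replicate 2 listed 5729. A lower contact depth of replicate 1 is consistent with the number n at the 194 loops with the same anchors in both. It was lower in replicate 1 at all 194, with a median ratio of 0.354 (quartiles 0.322 and 0.408), if n counts contacts. No biological explanation was tested, since the design has 1 group.

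X had fewer loops per Mb than each autosome in both replicates. The test set beforehand for its low gene content did not settle it. X had 14.4 loops per 100 protein-coding genes in replicate 2, and the lowest autosome (7) had 16.8. The exact Poisson interval for X, 12.1 to 17.0, reached that value (a normal approximation, used at first, ended at 16.8, just below it). Chromosome 7 had the most protein-coding genes per Mb, 14.2. The next lowest autosome (17) had 19.98 loops per 100 genes, so the interval reached chromosome 7 alone. The test was set on the lowest autosome, and its result stayed borderline. A comparison added because that result was borderline, when X was known to lie below each autosome, argues against gene density as the whole cause: chromosome 12, with 5.79 protein-coding genes per Mb against 5.74 on X, had 2.03 loops per Mb and X had 0.829 (Poisson interval 0.697 to 0.979). A lower contact depth on X, as a single copy in the cells might give, stays open: 56.8% of its replicate 2 loops (Wilson interval 48.5 to 64.8%) were on 25 kb anchors, above each autosome (31.9 to 49.8%) but with an interval that reaches chromosome 13. A biological difference in folding of X was not tested.

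Stem and progenitor regulators were enriched at anchors, and no biological explanation was tested. Local gene density and gene length are argued against, since the list's 55% lay at percentile 100 of 10000 matched random lists, whose mean was 23.4%. Leaving the 1461 olfactory and vomeronasal receptor genes out of the background moved the share of other genes only from 22.5 to 23.9%. The 55% is the list's own share and does not depend on the background. These families thus account for little of its gap to the other genes. The adjusted p without them, 0.000411 in Fisher's exact test, adds little, since so small a move could hardly change it. Only these families were left out. Wide anchors are argued against by an adjusted p of 0.000104 in the same exact test on the high-setting lists. Without its Hox genes the list still had 20 of 37 members at anchors (odds ratio 4.06). The list was picked from general knowledge of blood cells and leans to well-studied genes, and that bias was not tested.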
